A study of Rattus norvegicus with 12 samples.

How the data were processed

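Total RNA from laryngeal muscle of male F344 rats was labelled with biotin and hybridised to 12 Affymetrix whole-transcript rat gene arrays, per the labels' protocols. Each specimen gave 30 to 50 mg of tissue, and 100 ng of total RNA entered labelling. The muscle was either the posterior cricoarytenoid (PCA), which abducts the vocal folds, or the adductor complex (AC). Animals had undergone unilateral transection of the recurrent laryngeal nerve, or the same approach without nerve injury, 1 week before. Groups and replicate numbers were taken from the sample titles, with 3 arrays per group. The labels give 10 animals per surgery group but neither which animal gave an array, nor whether specimens were pooled, nor whether PCA and AC arrays share animals.

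The authors deposited 1 log2 expression value per probe set and array; the log base is not stated, and was taken as 2 from the range of the values (2.57 to 14.04) and from the named method. RMA and Partek are named in the submitters' processing notes, without version, role or order; RMA is known to end in quantile-normalised log2 values. Background step, probe filter and annotation version are not given in the sources used here. All deposited values have at most 2 decimals. Array medians lay between 7.11 and 7.17. Quantile normalisation compresses large differences in total RNA content between specimens, so changes are relative to the other genes of an array. Arrays carry no read depth, and their number limits the precision: the residual degrees of freedom were 8, with 3.14 prior degrees of freedom from limma.

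Of 27342 probe sets, the platform annotation gives 15103 a single gene symbol, 317 several and 11922 none. The last 2 kinds entered no gene test. Symbols were checked through gene identifiers against the rat RefSeq annotation of GRCr8, used for names only: 15067 matched, 36 did not and kept the annotation's symbol, and 0 changed. For the 500 genes with several probe sets, the one with the highest mean over all arrays was used, which left 14329 genes. No such gene had probe sets called in opposite directions in the comparisons of injury with control in PCA, of injury with control in AC, or of both muscles in controls. No coordinates are given, since the build behind the annotation is not stated. Genes of near-identical families, such as histones, share probe sequence and are uncertain one by one.

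One limma model (version 3.58.1, R 4.3.3) with a mean for each of the 4 groups was fitted to all 12 arrays with lmFit and eBayes, without a filter on dim probe sets. Its contrasts were injury against control in each muscle, the average and the difference of both injury effects, and PCA against AC in controls and in injured animals. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The injury effects were also compared across genes by correlation, covariance and overlap of calls. In each comparison, 37 gene lists fixed beforehand were tested with camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry as alternatives. Each list also has a count of members past the threshold over all genes and adjusted over the list alone. A marker score is the mean log2 value of a list's genes in an array. Python 3.11.15 with matplotlib 3.10.9 drew the plots.

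Design, gene lists, alternatives and naming rule were written before the data were examined. The rule names the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups do not overlap, for injury in PCA, injury in AC and PCA against AC in controls. It names 5 each way for the other comparisons, or the 5 with the smallest p where under 3 pass. Symbols of unnamed or microRNA loci were left out. From each list it takes the 3 members with the smallest adjusted p and the first listed, of which 2 to 4 may be named. Myosin heavy chains and receptor subunits may be named in full. Fbxo32 and the genes of the last part of the closing section were chosen after their values were seen.

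The fit was tested on simulated data in which 200 of 14329 genes were changed by 1.5-fold, 2-fold or 4-fold. Each gene had its real mean and residual spread, the same in all groups before the change. Noise was independent between genes, without the array or tissue effects that genes share, so recovery in the real data may be lower. For injury in PCA the fit recovered 61.2%, 83.6% and 98.5% of genes at these sizes. For injury in AC it recovered 73.1%, 85.1% and 95.5%, for the difference of the injury effects 35.8%, 70.1% and 97%, and for PCA against AC in injured animals 64.2%, 85.1% and 93.9%. Alternatives covered normalisation, filters on dim genes, probe set choice, the prior, array weights, replicate blocks, thresholds, the groups fitted and leaving out each array. After seeing the data, alternatives were added for 3 arrays with high thyroid and parathyroid transcripts, for a pair of injured arrays, and for marker scores as covariates. The lists cover junction, denervation, atrophy, proteasome, lysosome, contractile, myogenic, metabolic, matrix, nerve, channel, growth arrest, cell cycle, immune and cytokine genes, and markers of cartilage, airway and squamous epithelium, thyroid and parathyroid, fat, vessels, fibroblasts, tendon and red cells. Scanner files were not used here.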

Results

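Gene expression was measured in rat laryngeal muscle 1 week after unilateral transection of the recurrent laryngeal nerve, the motor nerve of both muscles studied, in which 1 cm of nerve was taken out. The posterior cricoarytenoid muscle (PCA) opens the vocal folds, and the laryngeal adductor complex (AC) closes them. Control rats underwent the same approach with the nerve left intact. The 12 whole-transcript arrays formed 4 groups of 3: PCA control, PCA injury, AC control and AC injury. Array medians lay between 7.11 and 7.17 on the log2 scale, and the number of arrays, not their depth, limited precision. The labels give 10 animals per surgery group but do not say whether each array came from a separate animal, so p-values measure the spread between these arrays, which may be technical. Values given below as a ± b are log2 differences with the SE from limma, n = 3 arrays per group. Genes named by size are those past the test whose groups did not overlap, all 3 arrays of one group lying above all 3 of the other.

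The first question was which transcripts in the PCA differed after nerve transection. In injured PCA, the 10 largest rises among genes named by size included those of Mmp12, a macrophage elastase (4.50 ± 0.55), Mmp9, a gelatinase (3.95 ± 0.42), Gpnmb, a glycoprotein of phagocytic myeloid cells (3.87 ± 0.36), and Il1rn, the interleukin-1 receptor antagonist (3.80 ± 0.39). Lilrb4, a leukocyte inhibitory receptor, rose by 3.71 ± 0.44. The remaining ones of the 10 were Stfa3, Serpinb12, Tgm3, Kprp and Cnfn (3.69 to 4.36), which are taken up below with the squamous epithelium markers. The 4 largest falls were in Ucp1, the brown-fat uncoupling protein (-3.46 ± 0.34), the extraocular-type myosin Myh13 (-2.67 ± 0.69), the slow myosin Myh7 (-2.60 ± 0.35) and Mstn, a secreted inhibitor of muscle growth (-2.51 ± 0.42). Mybphl, Scrg1, Fabp3, Pip, Serpina6 and Clec3a also fell (-2.45 to -2.16). In total 3697 of 14329 genes passed the limma test at an adjusted p of 0.05, 1900 higher and 1797 lower, and 453 and 199 of these changed at least 2-fold. All 3 injured arrays lay on one side of all 3 controls for 37% of genes, against 10% by chance. The count was 2257 with the 2 PCA groups fitted alone, 2335 without 3 arrays with high thyroid and parathyroid transcripts, and 639 with the squamous epithelium score of each array as a covariate. That score itself differed between the PCA groups (mean 8.34 in controls, 10.36 in injured), so as a covariate it also takes precision from the comparison.

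Several genes of the neuromuscular junction and of the denervation response rose in injured PCA. The acetylcholine receptor subunits Chrna1 (1.96 ± 0.37), Chrnd (1.47 ± 0.31) and the fetal subunit Chrng (1.41 ± 0.29) rose, as did Musk, the receptor kinase that clusters them (1.02 ± 0.21). Chrnb1 (0.10 ± 0.21) and the adult subunit Chrne (-0.16 ± 0.11) did not pass. Over the 17 measured junction genes 6 rose and 2 fell (6 and 3 adjusted over the list alone), and camera did not call the list (adjusted p = 0.27). Of 12 denervation-response regulators 7 rose and 1 fell (7 and 1 adjusted over the list alone), among them Myog, the myogenic factor that drives receptor genes (1.26 ± 0.29), Ncam1 (1.46 ± 0.22) and Cdkn1a (1.10 ± 0.21). Camera called that list (adjusted p = 0.0023; adjusted p = 0.312 with an estimated correlation). Among 11 embryonic and cardiac isoforms 4 rose and 1 fell, also adjusted over the list alone, including the fusion factor Mymk (2.73 ± 0.31), embryonic Myh3 (1.89 ± 0.31) and cardiac troponin Tnnt2 (1.73 ± 0.19); the list was not called (adjusted p = 0.227, direction up, although its median was -0.04). Of 19 satellite cell factors 5 rose and 3 fell, also adjusted over the list alone, with Myf5 at 0.81 ± 0.14 and Hgf at 0.79 ± 0.12, and the list was not called (adjusted p = 0.295).

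**Figure D1:**
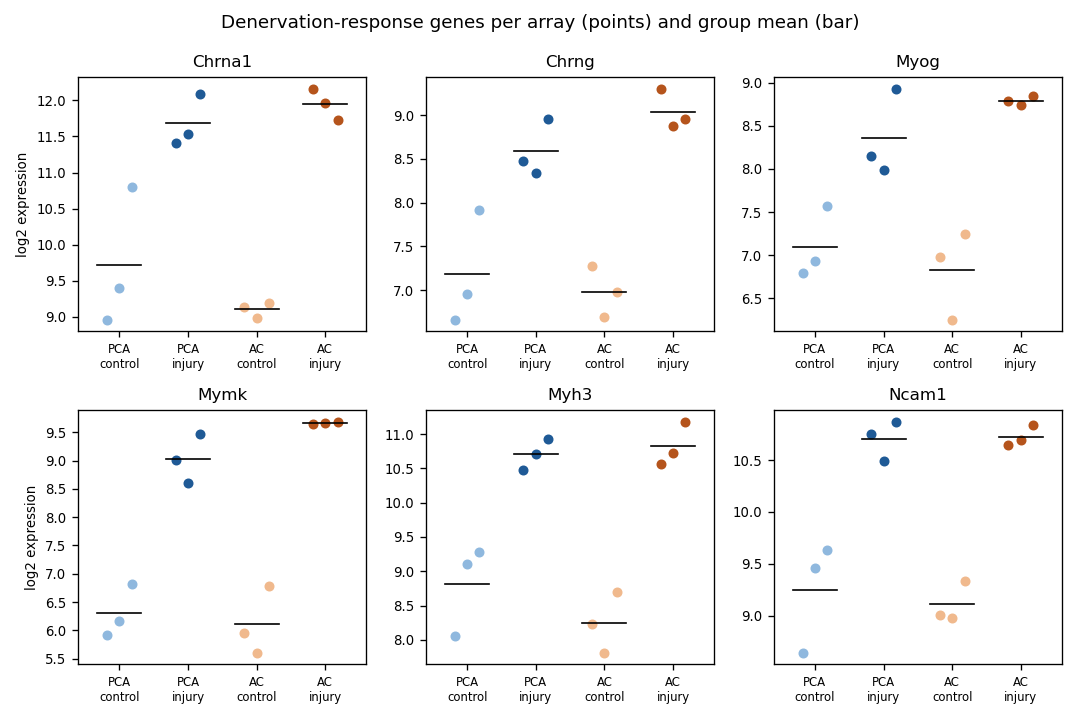
Log2 expression of 6 denervation-response genes (Chrna1, Chrng, Myog, Mymk, Myh3 and Ncam1) in each of the 12 arrays, by group; points are arrays and bars are group means. In all 6 genes, the 3 injured arrays of each muscle lie above the 3 control arrays of that muscle.

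Several contractile genes fell in injured PCA. Of 8 myosin heavy chains 5 fell and 1 rose (6 and 1 adjusted over the list alone): besides Myh13 and Myh7, Myh2 (-1.86 ± 0.24), Myh1 (-0.51 ± 0.16) and Myh6 (-0.49 ± 0.10) fell, Myh4 (-0.84 ± 0.29) and Myh7b (-0.20 ± 0.10) did not pass, and Myh3 rose. The fall was uneven between arrays: Myh13 stood at 6.55, 8.03 and 10.32 in PCA injury 1, 2 and 3, against 10.51 to 11.23 in the PCA controls. Of 13 fast-fibre genes 6 fell, also adjusted over the list alone, among them the fast troponins Tnnc2 (-0.86 ± 0.21) and Tnni2 (-0.72 ± 0.23). Of 13 slow-fibre genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), with the slow myosin light chain Myl2 at -2.04 ± 0.25 and the calcium pump Atp2a2 at -0.61 ± 0.08. The camera adjusted p was 0.00684 for myosins, 0.00434 for fast and 0.00744 for slow fibres (adjusted p = 0.304, 0.494 and 0.392 with an estimated correlation). Of 19 muscle ion channels 10 fell and 1 rose (11 and 1 adjusted over the list alone), among them the potassium channel Kcnma1 (-1.73 ± 0.20) and the chloride channel Clcn1 (-1.67 ± 0.25); camera called the list (adjusted p = 0.00207; adjusted p = 0.392 with an estimated correlation). PCA injury 3 did not show the fall of the fast-fibre and ion channel lists. Its mean log2 over the members was 11.82 and 9.53, within the 11.70 to 11.94 and 9.47 to 9.72 of the PCA controls, whereas PCA injury 1 and 2 lay below them (10.71 and 11.09; 8.80 and 8.98). On these means the exact two-sided permutation p was 0.3 and 0.2, where 0.1 is the smallest that 3 against 3 arrays allow, and fry gave an adjusted p of 0.0755 and 0.0156. Of 22 atrophy genes 9 fell and 1 rose (10 and 2 adjusted over the list alone). The members that fell included the ubiquitin ligase Trim63 (-1.13 ± 0.21), known to mark proteins for breakdown in wasting muscle, Klf15 (-0.85 ± 0.11) and the stress factor Atf4 (-0.50 ± 0.06). Camera called this list lower (adjusted p = 0.00684; adjusted p = 0.304 with an estimated correlation). Fbxo32, the other muscle ligase, was named after its value was seen and fell by 0.66 ± 0.18.

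**Figure D2:**
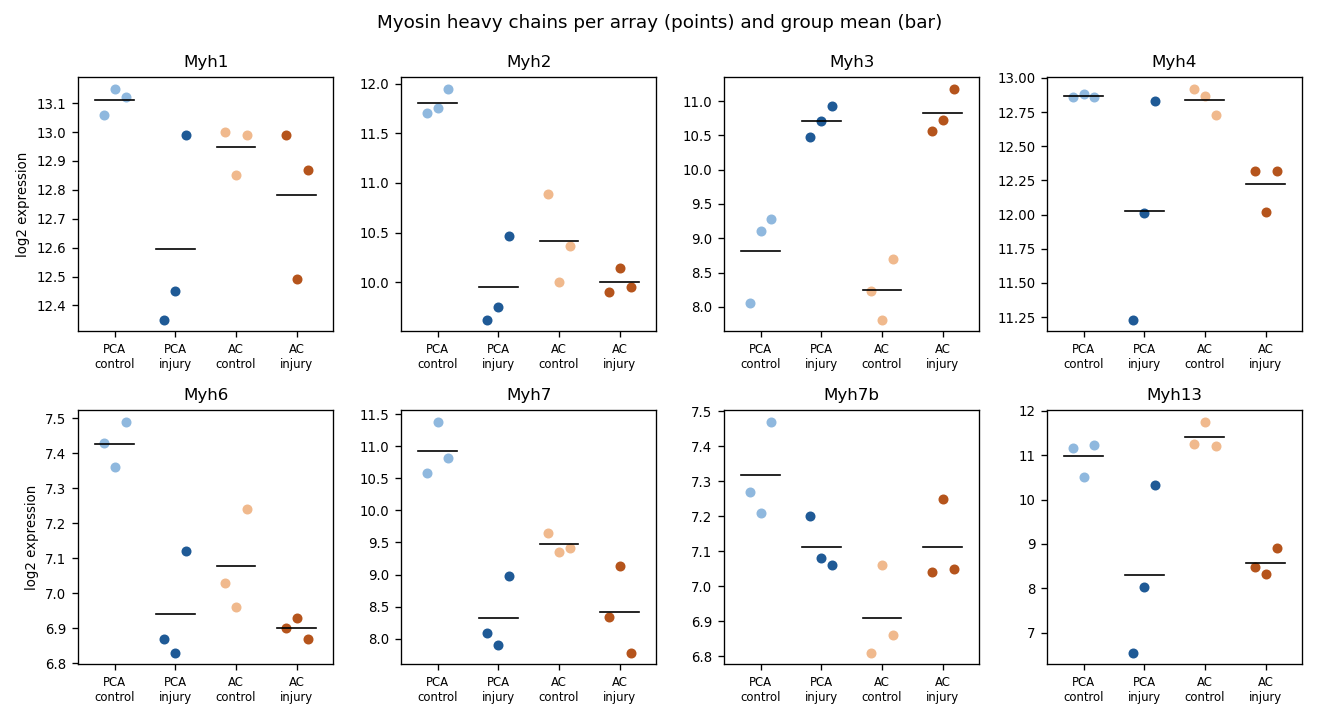
Log2 expression of 8 myosin heavy chain genes in each of the 12 arrays, by group; points are arrays and bars are group means. Myh3 is higher in the injured arrays of both muscles, and Myh7 and Myh2 are highest in the PCA controls.

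Genes of energy metabolism fell in injured PCA. All 19 measured genes of the tricarboxylic acid cycle fell, also adjusted over the list alone, with Dld at -0.91 ± 0.11 and Pdha1 at -0.81 ± 0.12. Of 50 oxidative phosphorylation genes 44 fell (48 adjusted over the list alone), among them the complex I subunit Ndufa5 (-0.95 ± 0.11) and the complex III subunit Uqcrfs1 (-1.10 ± 0.13). Of 26 fatty acid genes 23 fell (25 adjusted over the list alone), including Fabp3, a fatty acid carrier (-2.29 ± 0.31), and Pdk4, a brake on pyruvate oxidation (-1.16 ± 0.14). Of 22 glycolysis genes 18 fell (21 adjusted over the list alone), with Fbp2 at -1.15 ± 0.15 and Hk2 at -0.90 ± 0.16. Camera called all 4 lists (adjusted p = 2.42e-11, 8.32e-20, 1.94e-13 and 2.14e-09), and none with an estimated correlation (adjusted p = 0.304, 0.304, 0.304 and 0.312). The fall was smallest in PCA injury 3. Its mean log2 over the glycolysis genes was 11.12, against 10.27 and 10.56 in PCA injury 1 and 2 and 11.38 to 11.51 in PCA controls. The adipocyte marker score was also lower in injured PCA (8.36 to 9.1, against 9.43 to 9.88 in controls). How far fat content contributes to these falls was not tested.

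Macrophage, chemokine, cell division and matrix genes rose in injured PCA. Of 19 macrophage markers 18 rose, also adjusted over the list alone, with Cd68 at 2.76 ± 0.27, Fcer1g at 2.29 ± 0.20 and Lyz2 at 2.03 ± 0.19. Of 21 cytokine genes 14 rose, also adjusted over the list alone, including the chemokines Ccl9 (2.74 ± 0.36) and Ccl2 (2.62 ± 0.29). Of 23 cell cycle genes 21 rose, also adjusted over the list alone, among them cyclin Ccna2 (1.81 ± 0.15), topoisomerase Top2a (1.57 ± 0.14) and Nusap1 (1.55 ± 0.14). Of 28 collagen and matrix genes 20 rose and 1 fell (22 and 1 adjusted over the list alone), with Tgfb1, a fibrosis-promoting cytokine, at 1.48 ± 0.12, Col1a1 at 0.84 ± 0.20 and Fmod, the member that fell, at -1.45 ± 0.14. Camera called these 4 lists (adjusted p = 7.60e-15, 1.37e-08, 6.52e-17 and 1.11e-09; each adjusted p = 0.304 with an estimated correlation). Of 25 autophagy and lysosome genes 9 rose and 1 fell, also adjusted over the list alone; the risers named were lysosomal proteases (Lgmn 1.67 ± 0.17, Ctss 1.07 ± 0.13, Ctsd 0.69 ± 0.09), and camera called the list (adjusted p = 0.00478; adjusted p = 0.304 with an estimated correlation). Of 30 proteasome subunits 2 fell and none rose (0 and 0 adjusted over the list alone), with no call (adjusted p = 0.987).

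Markers of tissues that adjoin the muscle also differed between injured and control PCA. Of 12 squamous epithelium markers 11 rose (12 adjusted over the list alone), with the keratin Krt14 at 2.14 ± 0.30 and Calml3 at 1.19 ± 0.23, and 5 of the 10 largest risers were Stfa3, Serpinb12, Tgm3, Kprp and Cnfn (3.69 to 4.36), of which Tgm3, Kprp and Cnfn are known from stratified epithelium. With the squamous score as a covariate the sign of these 5 turned, though none passed the test that way. Of 17 cartilage markers 15 fell and 1 rose (16 and 1 adjusted over the list alone), with Clec3a at -2.16 ± 0.32 and Chad at -1.29 ± 0.13. Of 17 adipocyte markers 12 fell (14 adjusted over the list alone), among them Ucp1 and the enzyme Pck1 (-2.04 ± 0.31). Camera called all 3 lists (adjusted p = 1.52e-06, 3.37e-08 and 1.52e-06; each adjusted p = 0.304 with an estimated correlation). The squamous score, a mean over the 12 markers, was 8.05, 9.59 and 7.39 in the PCA controls, 10.00 to 10.66 in injured PCA, and 10.59 to 11.11 in the AC controls. The thyroid and parathyroid score was 9.69 in PCA control 1, 9.51 in PCA injury 2 and 8.30 in AC injury 2, and 6.29 to 7.10 in the other arrays; of its 15 genes 0 passed in the PCA by limma (0 adjusted over the list alone, and 0 at an unadjusted p under 0.05).

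**Figure D3:**
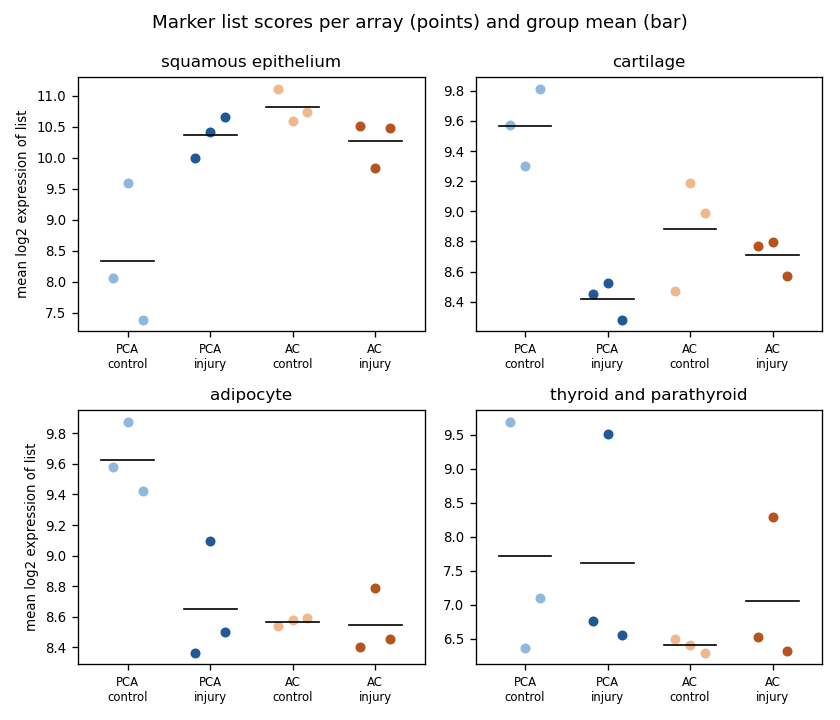
Mean log2 expression of the squamous epithelium, cartilage, adipocyte and thyroid and parathyroid marker lists in each of the 12 arrays, by group; points are arrays and bars are group means. The 3 PCA controls have the lowest squamous scores, and 3 arrays from 3 groups have thyroid and parathyroid scores above 8.

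Of 18 genes of injured-nerve Schwann cells 6 rose in injured PCA (7 adjusted over the list alone), with the stress factor Atf3 at 1.26 ± 0.12. Of 14 fibroblast markers 6 rose (7 adjusted over the list alone), with Cthrc1 at 2.61 ± 0.38. Of 9 tendon markers 6 fell and 2 rose, also adjusted over the list alone, with Prg4 at -1.46 ± 0.22. Of 16 lymphocyte markers 4 rose and 1 fell, also adjusted over the list alone, with Cd4 at 1.20 ± 0.19. Camera called these 4 lists (adjusted p = 0.011, 0.0069, 0.0302 and 0.0336; adjusted p = 0.304, 0.304, 0.411 and 0.392 with an estimated correlation). Lists not called included 27 neurotrophic factors (7 rose, 3 fell; 8 and 7 adjusted over the list alone; Mdk 1.21 ± 0.17), 28 axon guidance genes (9 and 3, also adjusted over the list alone; Ephb2 0.84 ± 0.14) and 20 growth arrest genes (8 and 4, also adjusted over the list alone; Gadd45g -0.80 ± 0.11). The same held for 18 polyamine and amino acid genes (2 rose, 6 fell; 2 and 7 adjusted over the list alone), 17 myelin genes (2 fell, also adjusted over the list alone; S100b -0.99 ± 0.15), 20 airway epithelium markers (1 rose, 5 fell, also adjusted over the list alone), 15 neutrophil and mast cell markers (2 rose, also adjusted over the list alone; Cxcr2 1.85 ± 0.25), 12 smooth muscle markers (2 and 2, also adjusted over the list alone), 11 endothelial and 7 red cell markers (0 passed in limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05). The camera adjusted p of these 10 lists ran from 0.0702 to 0.987. Its direction was up for neutrophil and mast cell and for endothelial markers although their medians were -0.01 and -0.03.

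The second question was which transcripts in the AC differed after transection. In injured AC, 7 of the 10 largest rises among genes named by size were in the fixed receptor, denervation and embryonic muscle lists: Mymk (3.56 ± 0.31), Chrna1 (2.84 ± 0.37), Myh3 (2.58 ± 0.31), Chrnd (2.31 ± 0.31), Chrng (2.06 ± 0.29), Tnnt2 (2.00 ± 0.19) and Myog (1.97 ± 0.29). Lilrb4 (2.50 ± 0.44), the steroid transporter subunit Slc51a (1.90 ± 0.24) and the kallikrein Klk1 (1.85 ± 0.41) also rose. The largest falls were in Ngp, a neutrophil granule protein (-3.19 ± 0.52), Ahsp, a chaperone of haemoglobin (-2.64 ± 0.34), Mybphl (-2.49 ± 0.38), the neutrophil peroxidase Mpo (-2.13 ± 0.29) and Defa5 (-1.99 ± 0.34). Sec14l3, Cyp2a3, Btn1a1, Perm1 and Adhfe1 also fell (-1.80 to -1.38). In total 274 genes passed, 165 higher and 109 lower, and 54 and 23 of these changed at least 2-fold. All 3 injured arrays lay on one side of the 3 controls for 28.4% of genes, against 10% by chance. The count was 619 with the 2 AC groups fitted alone, 703 with array weights, 92 with the squamous score as a covariate and 10 without the 3 arrays with high thyroid and parathyroid transcripts. With single arrays left out it was 41, 14 and 127 without AC control 1, 2 and 3, 13 and 52 without AC injury 2 and 3, 169 and 146 without PCA control 2 and 3, and 663 and 622 without PCA injury 1 and 3; the PCA arrays enter only through the shared estimate of the spread.

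Of the 12 denervation-response regulators 7 rose in the AC (9 rose and 1 fell adjusted over the list alone), with Ncam1 at 1.62 ± 0.22 and Gadd45a at 1.27 ± 0.17. Of the 17 junction genes 4 rose, also adjusted over the list alone: Chrna1, Chrnd, Chrng and Musk (1.21 ± 0.21), while Chrnb1 was at 0.31 ± 0.21 and Chrne at 0.25 ± 0.11. Of 11 embryonic and cardiac isoforms 3 rose (5 adjusted over the list alone). Of 19 satellite cell factors 5 rose (6 adjusted over the list alone), with Myf5 at 0.91 ± 0.14 and Fgfr4 at 0.63 ± 0.10. Camera called the regulators, isoforms and satellite cell lists (adjusted p = 9.28e-08, 6.76e-05 and 0.00146; each adjusted p = 0.328 with an estimated correlation), but not the junction list (adjusted p = 0.0663). Among the 8 myosins only Myh3 passed (1 rose; 1 rose and 2 fell adjusted over the list alone), with Myh13 at -2.82 ± 0.69, Myh7 at -1.05 ± 0.35, Myh4 at -0.62 ± 0.29, Myh2 at -0.42 ± 0.24, Myh6 at -0.18 ± 0.10, Myh1 at -0.16 ± 0.16 and Myh7b at 0.20 ± 0.10. Of 13 slow-fibre genes 2 rose (4 rose and 2 fell adjusted over the list alone), Casq2 (1.84 ± 0.28) and the slow troponin Tnni1 (1.24 ± 0.20), and 0 of 13 fast-fibre genes passed in limma (0 adjusted over the list alone, and 0 at an unadjusted p under 0.05). Camera called the fast-fibre list lower (adjusted p = 0.0259; adjusted p = 0.57 with an estimated correlation), but not the myosins (adjusted p = 0.188) or the slow-fibre list (adjusted p = 0.223).

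Metabolic genes lay lower in injured AC, though few passed gene by gene. Of 50 oxidative phosphorylation genes 1 fell (22 adjusted over the list alone), Ndufs7 (-0.63 ± 0.13). Of 19 tricarboxylic acid cycle genes 0 passed in limma (17 fell adjusted over the list alone, 17 at an unadjusted p under 0.05, median -0.47), as did 0 of 26 fatty acid genes (15 fell adjusted over the list alone, 15 at an unadjusted p under 0.05, median -0.37). Of 22 glycolysis genes 3 fell (14 adjusted over the list alone): Ldha, lactate dehydrogenase (-0.97 ± 0.17), Fbp2 (-0.80 ± 0.15) and Phkg1 (-1.16 ± 0.24). Camera called the 4 lists (adjusted p = 4.59e-18, 1.98e-12, 2.41e-10 and 1.50e-11; adjusted p = 0.329, 0.328, 0.328 and 0.329 with an estimated correlation). Of 19 macrophage markers 3 rose (15 adjusted over the list alone), Cd68 (1.28 ± 0.27), Fcer1g (1.00 ± 0.20) and Aif1 (0.84 ± 0.17). Of 28 matrix genes 2 rose (20 rose and 1 fell adjusted over the list alone), Timp1 (1.23 ± 0.24) and Tgfb1 (0.71 ± 0.12). Of 21 cytokine genes 2 rose (14 adjusted over the list alone), Tnfrsf12a (0.84 ± 0.13) and Il6r (0.40 ± 0.09). Camera called these lists too (adjusted p = 7.45e-11, 2.22e-09 and 3.07e-09; adjusted p = 0.328, 0.329 and 0.328 with an estimated correlation).

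Of 23 cell cycle genes 0 passed in the AC by limma (0 adjusted over the list alone, 6 at an unadjusted p under 0.05, median 0.25), although camera called the list (adjusted p = 8.69e-05; adjusted p = 0.389 with an estimated correlation). Of 7 red cell markers 3 fell (5 adjusted over the list alone), Ahsp, Slc4a1 (-1.30 ± 0.24) and Rhag (-0.71 ± 0.12). Of 15 neutrophil and mast cell markers 2 fell (3 fell and 1 rose adjusted over the list alone), Ngp and Mpo. Both lists were called (adjusted p = 4.14e-07 and 0.000735; each adjusted p = 0.328 with an estimated correlation). Of 22 atrophy genes 2 rose (2 rose and 3 fell adjusted over the list alone), the metallothioneins Mt2A (0.90 ± 0.14) and Mt1 (0.90 ± 0.16), which bind metals. Trim63 was at -0.54 ± 0.21 (adjusted p = 0.181 by limma) and the list was not called (adjusted p = 0.124). Squamous (median -0.35), cartilage (median -0.24), adipocyte (median 0.00) and thyroid and parathyroid (median 0.42) markers had 0 genes past the limma test (0 adjusted over the list alone in each, and 1, 2, 1 and 1 at an unadjusted p under 0.05), and of these camera called the squamous list lower (adjusted p = 0.0217; adjusted p = 0.57 with an estimated correlation). For neurotrophic factors and tendon markers the camera direction was up although the medians were -0.01 and -0.10, and neither was called (adjusted p = 0.975 and 0.9).

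The injury effects of both muscles were then set side by side. Across genes, which are not independent replicates, they correlated at r = 0.505 (rho = 0.505; covariance 0.0685). Higher in both muscles were 134 genes and lower in both 86, against 21.9 and 13.7 for independent lists of these sizes. The muscles shared no arrays, but both tests used the same estimate of the spread for a gene. Genes of small spread are thus more easily called in both, so 21.9 and 13.7 may be too low a reference. The 134 and 86 moved with single arrays. Without PCA control 1, 2 and 3 they were 111 and 57, 97 and 40, and 81 and 32, and without AC control 1, 2 and 3 they were 24 and 8, 5 and 3, and 78 and 28. Without PCA injury 1, 2 and 3 they were 279 and 190, 106 and 53, and 231 and 287, and without AC injury 1, 2 and 3 they were 253 and 87, 6 and 3, and 22 and 13. Of the 274 AC calls, 263 (96%) had the same sign in the PCA, and 84.7% of the PCA calls had the same sign in the AC. Over all genes the share was 65.1%. The 1 gene called in opposite directions was the potassium channel subunit Kcns2. Averaged over both muscles, 3790 genes passed, 1915 higher and 1875 lower, with 48 of 50 oxidative phosphorylation genes and all 19 tricarboxylic acid cycle genes lower, 18 of 19 macrophage markers and 24 of 28 matrix genes higher, and 8 of 12 denervation regulators higher (50, 19, 18, 24 and 9 adjusted over the list alone). Camera called 23 lists in the average and 0 with an estimated correlation (lowest adjusted p = 0.29).

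**Figure D4:**
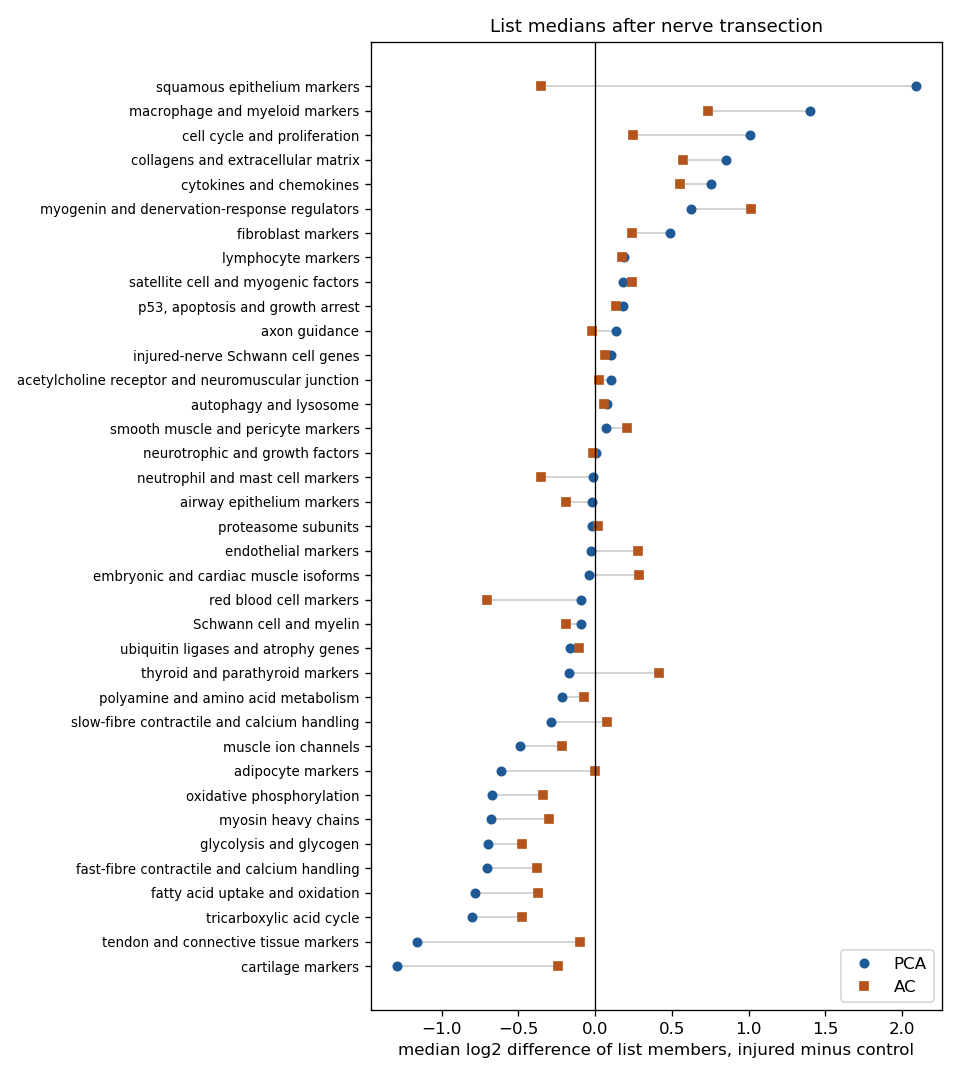
Median log2 difference, injured minus control, of the measured genes of each of the 37 lists, in PCA and AC. Denervation regulators have medians of 0.63 and 1.02, the tricarboxylic acid cycle -0.80 and -0.47, and the squamous list 2.09 and -0.35.

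The difference of the injury effect between the muscles was tested directly, as AC minus PCA. Ucp1 (3.55 ± 0.49), cardiac and slow troponin Tnnc1 (2.00 ± 0.31), Vsig2 (1.02 ± 0.13) and Kcns2 (0.53 ± 0.09) had the more positive effect in the AC. Il1rn (-3.68 ± 0.55), Rab7b (-1.50 ± 0.24), Ccna2 (-1.37 ± 0.21), Top2a (-1.34 ± 0.19) and the histone Hist1h2ail1 (-1.33 ± 0.16) had the more positive effect in the PCA. Part of this lies in the controls. There Ucp1 and Tnnc1 were higher in PCA by 3.79 and 1.77, while 0 genes differed past the test in injured animals. The cell cycle score averaged 6.83 in PCA controls, 7.72 in AC controls, and 7.855 and 7.96 in injured PCA and AC. This contrast cannot tell a different response to injury from different control specimens. In all 22 genes passed, 4 and 18, and 3 of 23 cell cycle genes were among the latter (18 adjusted over the list alone). Camera called the cell cycle list (adjusted p = 5.95e-19; adjusted p = 0.217 with an estimated correlation), and it was the 1 list that fry called of 22 that camera did. The squamous list moved the same way, with a median of -2.79 and 12 of 12 markers lower adjusted over the list alone (0 over all genes by limma, 12 at an unadjusted p under 0.05; adjusted p = 7.74e-12 by camera, 0.0537 by fry; adjusted p = 0.217 with an estimated correlation). For the receptor genes the difference did not pass (Chrna1 0.88 ± 0.52, adjusted p = 0.449; Chrnd adjusted p = 0.378; Chrng adjusted p = 0.48 by limma). The count was 0 with the squamous score as a covariate, 0 without the 3 arrays with high thyroid and parathyroid transcripts, 348 with array weights and 143 without genes below the median expression level. Since the squamous list itself ran with this contrast, its score as a covariate also costs precision. With single arrays left out it was 6, 406 and 1 without PCA control 1, 2 and 3, 0, 5 and 0 without AC control 1, 2 and 3, 7, 12 and 8 without PCA injury 1, 2 and 3, and 0 and 3 without AC injury 1 and 2.

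The next comparison asked how the muscles differ without injury, and shares its PCA control arrays with the first. In controls, PCA held more Ucp1 (3.79 ± 0.34), Serpina6 (2.55 ± 0.39), Scrg1 (2.48 ± 0.45), slow troponin Tnnc1 (1.77 ± 0.22) and the cartilage genes Col10a1 (1.90 ± 0.43) and Acan (1.62 ± 0.35) than AC. Scd, Ankef1, Adipoq and Plin1 were higher by 1.54 to 1.65. PCA held less Stfa3, Serpinb2, Cnfn, Serpinb12, Clca4l, Klk10, Kprp, Tgm3 and Sprr3 (-4.70 to -3.92), among them Sprr3, Cnfn and Tgm3 of stratified epithelium, and less Ngp (-4.38 ± 0.52). With the squamous score as a covariate the sign of Stfa3, Serpinb2, Cnfn, Serpinb12, Kprp, Tgm3 and Sprr3 turned, though none passed the test that way. Sprr3 is itself part of that score. Of 13 slow-fibre genes 7 were higher in PCA (12 adjusted over the list alone), with Tnnt1 at 1.17 ± 0.19 and Tnni1 at 1.22 ± 0.20, and of 13 fast-fibre genes 0 passed in limma (0 adjusted over the list alone, 1 at an unadjusted p under 0.05). The myosins Myh7 (1.46 ± 0.35), Myh2 (1.39 ± 0.24), Myh7b (0.41 ± 0.10) and Myh6 (0.35 ± 0.10) were higher, 4 of 8 (4 adjusted over the list alone). Camera called the slow-fibre and myosin lists (adjusted p = 4.48e-08 and 0.0121; adjusted p = 0.254 and 0.355 with an estimated correlation).

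Of 23 cell cycle genes 20 were lower in control PCA than in control AC, also adjusted over the list alone, among them Top2a (-1.55 ± 0.14) and Ccna2 (-1.52 ± 0.15). Of 19 macrophage markers 5 were lower (15 adjusted over the list alone). Of 12 squamous markers 11 were lower (12 adjusted over the list alone), and of 17 cartilage markers 9 were higher and 1 lower (11 and 1 adjusted over the list alone). Of 17 adipocyte markers 11 were higher (14 adjusted over the list alone), and of 15 neutrophil and mast cell markers 7 were lower, also adjusted over the list alone. Camera called these 6 lists (adjusted p = 1.03e-20, 1.94e-08, 5.72e-11, 2.40e-05, 3.95e-09 and 1.47e-07 in that order; adjusted p = 0.172, 0.355, 0.254, 0.355, 0.31 and 0.172 with an estimated correlation). In total 1523 genes passed, 464 higher and 1059 lower in PCA; with each array centred on its median the split was 668 and 930. The count was 2 with the squamous score as a covariate, 812 without the 3 arrays with high thyroid and parathyroid transcripts, 2436 over every row of the value table and 2626 with array weights. The squamous score itself differed between the control groups (mean 8.34 in PCA, 10.81 in AC). As a covariate it therefore also takes precision from this comparison. The count of 2 cannot be read as the share of differences due to mucosa. It was 881 and 805 without PCA control 1 and 3, and 714 and 797 without AC control 1 and 3.

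In injured muscle, no gene differed between PCA and AC at an adjusted p of 0.05 by limma; 517 had an unadjusted p under 0.05, and the smallest adjusted p was 0.16, for Vsig2 (-0.70 ± 0.09, higher in AC). The next by p, none past the test, were Sctr (1.30 ± 0.23), Or5aq1b (-0.39 ± 0.07) and Zbtb16, each with an adjusted p of 0.522 by limma, and Cmahp (-0.95 ± 0.18). Camera called 11 of 37 lists and fry 0; the lowest camera value was for oxidative phosphorylation, lower in PCA (median -0.13, adjusted p = 6.88e-07; adjusted p = 0.886 with an estimated correlation). Groups did not overlap for 6.5% of genes, against 10% by chance. All 6 injured arrays correlated best over all genes with an array of the other muscle. PCA injury 1 and 2 did so with AC injury 2 (0.9928 and 0.9909), AC injury 1 and 3 with PCA injury 3 (0.9938 and 0.9946), PCA injury 3 with AC injury 3 and AC injury 2 with PCA injury 1. Without PCA injury 3 and AC injury 2, left out after seeing the data as the best matches of the other 4 injured arrays, which by itself favours a difference, 38 genes passed.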

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

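Tests of explanations in this part were all chosen after the patterns were seen, as was the count of splits for genes that differ between PCA and AC in injured animals; the other counts of splits were planned.

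The injury effect differed between the muscles for 22 genes by the limma interaction test, given as AC minus PCA on the log2 scale. Ucp1 (3.55), Tnnc1 (2.00), Vsig2 (1.02) and Kcns2 (0.53) had positive differences. Il1rn (-3.68), Rab7b (-1.50), Ccna2 (-1.37), Top2a (-1.34) and Hist1h2ail1 (-1.33) had negative ones. Ucp1 and Tnnc1 already differed between the muscles in controls (3.79 and 1.77, PCA minus AC), so these differences need not be responses to injury. Of 100 splits within each muscle, drawn from 200, 8 gave as many genes, the real one included, and the highest other gave 2202. That other split kept the PCA arrays as labelled and mixed those of the AC, so it carries the injury effect of the PCA into the difference. Such splits test for no injury effect rather than for equal effects, and leave open whether the difference is due to chance.

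The interaction also shifted 22 lists by camera, and 3 of the 100 splits gave as many, with 23 in the highest other, which leaves chance open for the same reason. Positive medians were found for cartilage (1.09), tendon (0.96), adipocyte (0.67), slow-fibre (0.60), fatty acid (0.43), myosin (0.38), tricarboxylic acid cycle (0.32), ion channel (0.30), oxidative phosphorylation (0.30), embryonic isoform (0.27) and atrophy genes (0.19). Negative medians were found for squamous epithelium (-2.79), cell cycle (-0.76), red cell (-0.71), macrophage (-0.68), neutrophil and mast cell (-0.36), collagen and matrix (-0.22), fibroblast (-0.21), axon guidance (-0.15), cytokine (-0.11), injured-nerve Schwann cell (-0.092) and lysosome genes (-0.073). With an estimated correlation 0 lists were called, with a lowest adjusted p of 0.217 by camera, and fry called 1.

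For the other comparisons, the numbers of splits were as follows. The 3697 genes and 22 lists of injury in PCA were each reached by 1 of 10 splits, the real one, with at most 0 genes and 20 lists in the others. The 274 genes and 18 lists of injury in AC were reached by 1 of 10, with at most 0 and 17. The 1523 genes and 21 lists of PCA against AC in controls were reached by 1 of 10, with at most 0 and 20. With 10 splits no share under 0.05 can be had. Of 100 splits within each muscle, 1 gave as many as the 3790 genes and 1 as many as the 23 lists of the averaged effect. The others gave at most 1142 genes and 22 lists. This argues against chance only as the lack of an injury effect in both muscles, and only if the arrays are independent, which the labels do not say. An effect in the PCA alone could give the same counts. The correlation of both injury effects, 0.505, was reached by 7 of the 100, with 0.654 in the highest other, so chance cannot be excluded for it.

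Squamous epithelium genes rose (median 2.09) and cartilage genes fell (median -1.29) after injury in PCA. A response of squamous epithelium to nerve injury shared by both muscles is argued against by the AC. There the median change was -0.35 (median SE 0.523) and 0 of 12 genes lay above 0. Markers of 1 tissue are not independent, and less mucosa in the injured AC specimens could hide such a response. Different amounts of mucosa and cartilage in the PCA specimens remain open: the range of the squamous genes within the 3 PCA controls was 1.145 times their change after injury, as a median over genes, and that of the cartilage genes 0.547 times theirs. Within AC controls the median range was 0.465, against 1.675 within PCA controls. A response in mucosa next to the PCA alone was not tested, and the drop of the PCA count from 3697 to 639 genes with the squamous score as a covariate removes any effect that runs along this score.

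PCA and AC differed in controls (1523 genes) and not in injured animals (0 genes). Thyroid and parathyroid transcripts in single arrays are argued against as the whole cause, as far as they follow a linear trend in their score, since with that score as a covariate 0 genes differed by limma. An exchange of labels between PCA injury 3 and AC injury 2, named from the same data, remains a candidate explanation: along the control difference PCA injury 1 and 2 and AC injury 2 lay apart from the other 3 injured arrays by 0.758 in correlation and by 0.369 on the slow-fibre minus fast-fibre score, and the split that joins those 3 gave 206 genes and 19 lists, whereas the labelled split was matched or passed by 10 of 10 splits in genes and 7 in lists. For PCA injury 3 the score gap came from its fast-fibre score, the highest of the injured arrays (11.82, against 10.71 to 11.49). On the slow-fibre score alone it was also the highest (10.03), with AC injury 1, 2 and 3 at 9.53, 9.98 and 9.725. An exchange does not predict that. Its myosin score (10.09) lay above all AC arrays (9.57 to 9.97), but also above PCA injury 1 and 2 (9.05 and 9.35). Myh13 does not decide the exchange. In PCA injury 3 (10.32) it lay above all 3 AC injured arrays (8.33 to 8.92), but also above PCA injury 1 and 2 (6.55 and 8.03). The squamous score was lower in PCA injury 1 and 2 and AC injury 2 (9.83 to 10.42) than in the other 3 injured arrays (10.48 to 10.66). Mucosa content may therefore contribute to the gap. A loss of differences between denervated muscles stays open as untested, and all results use the labels as deposited.

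Genes of granulocytes and red cells fell after injury in AC, with Ngp at -3.19 and Ahsp at -2.64. Bone marrow in the AC control specimens would raise precursor genes in all 3 of them. All 3 AC controls lay above the other 9 arrays for 5 of 32 precursor genes of 4 lineages (15.6%). That is far from most of the genes. The share would be 0.455% if all arrays were interchangeable. They were not: AC controls did not overlap PCA controls for 33.7% of all genes, nor injured AC for 28.4%. The share among all genes was not counted, so whether 15.6% is more than usual cannot be told. Of the 32, Epb42 and Rhag belong to the fixed red cell list in which the pattern was seen, and both are among the 5. The test therefore leaves bone marrow open. More blood in those specimens could also lower such genes. The 4 haemoglobin genes, of which Hbb and Hbb-b1 also belong to that red cell list, had a median change of -0.62. It was further below 0 than the -0.252 of the red cell precursor genes, which is what more blood predicts against that set. The set includes genes bright in all 4 groups, such as Tmod1 (10.88 to 11.16). Against Ahsp (-2.64) and Rhag (-0.71), red cell genes that passed in the AC, the haemoglobin change was the smaller one. The haemoglobin median also lay within 2 of the genes' SE of 0. This requirement, added after the value was seen, is what turned the test from one in favour to one that leaves more blood open. Neither marrow nor blood can be told apart from a change in circulating cells, which was not tested.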

How the results depend on the processing

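Alternatives that leave out the 3 arrays with high thyroid and parathyroid transcripts, leave out PCA injury 3 and AC injury 2, or use marker scores as covariates were chosen after seeing the data; the others were planned. Causes were not tested, except that a stricter threshold lowers a count by construction. The squamous score differed between the groups compared in PCA and in controls, so as a covariate it lowers precision and can lower counts without changing effects much. In controls, 18 of 31 histone genes, taken up below, were lower in PCA without the score and 0 with it. Their median only went from -0.493 to -0.467.

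The number of genes for injury in PCA (3697) was 2257 with its 2 groups alone, 1865 at an adjusted p of 0.01, 652 with at least a 2-fold change, 2335 without the 3 arrays, 639 with the squamous score and 765 with both scores. For injury in AC (274) it was 619 with 2 groups, 703 with array weights, 17 at 0.01, 77 with 2-fold, 10 without the 3 arrays, 70 without the pair, 417 with the thyroid and parathyroid score, 92 with the squamous score and 157 with both. For the averaged effect (3790) it was 2065 at 0.01 and 247 with 2-fold. For the difference of the effects (22) it was 35 after quantile normalisation, 143 without genes below the median level, 84 over every row, 35 with a trended robust prior, 348 with array weights, 0 at 0.01, 0 without the 3 arrays, 0 without the pair, 42 with the thyroid and parathyroid score, 0 with the squamous score and 0 with both. For PCA against AC in controls (1523) it was 2436 over every row, 2626 with array weights, 560 at 0.01, 359 with 2-fold, 812 without the 3 arrays, 2 with the squamous score and 2 with both. For PCA against AC in injured animals (0) it was 38 without the pair. In the alternatives run, the correlation of both effects stayed within 0.19 of its value of 0.505. That bound is a jackknife SE computed from the left-out arrays. It is wider than the range of the correlation with single arrays left out (0.41 to 0.578), so it is a lenient one.

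With single arrays left out, counts ranged from 2466 to 3558 (PCA), 13 to 663 (AC), 3034 to 3920 (averaged), 0 to 406 (difference), 714 to 1813 (controls) and 0 to 0 (injured), and the correlation from 0.41 to 0.578. Lists called ranged from 21 to 23, 15 to 23, 20 to 25, 14 to 26, 15 to 26 and 4 to 21 in the same order. The 14 came without PCA injury 1, and in injured animals the lists were 4, 21 and 5 without PCA injury 2, PCA injury 3 and AC injury 1.

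With an estimated correlation camera called 0 lists for injury in PCA, 0 in AC, 0 averaged, 0 for the difference, 0 in controls and 0 in injured animals. Fry called 1 for the difference, 11 in controls and 0 in injured animals. In injured animals camera called 20 lists without the pair and 7 with both scores.

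With the replicate number as a fixed block, 59 genes were called in AC and 0 for the difference, and 12 for the difference with a random block of numbers within a treatment. The numbers were not taken as pairs, since the labels do not say that a number is shared by an animal. Of 12 same-numbered pairs, 4 had deviations correlated above 0.1 (-0.39 to 0.34). Some of these pairs set a control against an injured array, which cannot share an animal. Injured PCA and AC arrays of numbers 1, 2 and 3 had -0.39, 0.34 and 0.27, so whether they share animals stays open. Not every array correlated best with its own number.

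With the squamous score as a covariate, the change after injury in PCA was -1.09 for Stfa3, -0.42 for Serpinb12, -0.55 for Tgm3, -0.22 for Kprp and -0.001 for Cnfn, and with both scores -1.43, -0.63, -0.72 and -0.35 for Stfa3, Serpinb12, Tgm3 and Kprp. In controls, PCA minus AC was 1.97 for Stfa3, 0.031 for Serpinb2, 0.18 for Cnfn, 1.12 for Serpinb12, 0.73 for Kprp, 1.24 for Tgm3 and 0.57 for Sprr3, and with both scores 2.09, 0.17, 1.20, 0.78, 1.30 and 0.61 for the same genes without Serpinb2. All 22 reversals arose with these scores, which rest on genes of the same tissue, and none of the reversed values passed the test. Of the named genes that passed, the squamous score ended the call of 40 of 93 in PCA, 22 of 53 in AC, 10 of 10 for the difference and 27 of 28 in controls, the reversed genes included. Leaving out the 3 arrays ended 13, 46, 10 and 9. Leaving out 1 array could end as many: 45 of 53 in AC without AC control 2, and 45 without AC injury 2. For the difference, all 10 ended without AC control 1, AC control 3 or AC injury 1, and 0 without PCA control 2. Across single arrays, 0 to 45 ended in AC, 0 to 6 in PCA and 0 to 9 in controls. The replicate number as a fixed block ended 1, 25, 10 and 1, and an adjusted p of 0.01 ended 12, 42, 10 and 11.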

Other observations

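Tests in this part, and the genes it names, were chosen after the values were seen.

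Core, linker and variant histone genes, many of which are known to be transcribed mainly in dividing cells, formed a group of 31 by their symbols. In injured PCA 17 were higher and 0 lower, with Hist1h2ail1 at 1.39 ± 0.11, Hist2h3c2 at 1.28 ± 0.10 and the linker histone H1f1 at 1.18 ± 0.13, as log2 difference and SE. In injured AC 0 passed in limma, and 3 had an unadjusted p under 0.05. The difference of the effects passed for 6 of the 31, all smaller in AC. In controls 18 were lower in PCA than in AC and 0 higher. With each array centred on its median, 17, 0, 5 and 17 passed in these 4 comparisons, and with the squamous score as a covariate 8, 0, 0 and 0, with 17, 3, 12 and 15 at an unadjusted p under 0.05 by limma. The squamous list ran the same way, with medians of 2.09 in injured PCA, -0.35 in injured AC, -2.79 for the difference and -2.47 for control PCA minus control AC. Medians of the 31 genes were 0.357, 0.04, -0.373 and -0.493 without that score and 0.409, 0.077, -0.365 and -0.467 with it. Probes of near-identical histone genes share sequence, so single members are uncertain, and the PCA comparison and the control comparison share the PCA control arrays.

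Outside the fixed lists and the genes named by size, 103 genes were higher and 72 lower in both muscles after injury. Without PCA control 1, 2 and 3 they were 83 and 47, 68 and 32, and 56 and 26, without AC control 1, 2 and 3 they were 10 and 7, 2 and 3, and 53 and 24, without PCA injury 1, 2 and 3 they were 230 and 147, 80 and 42, and 189 and 205, and without AC injury 1, 2 and 3 they were 203 and 76, 2 and 3, and 11 and 10. Ranked by the smaller of both changes, the first higher genes were the protease inhibitor Cst7 (2.07 in PCA, 1.84 in AC), the lectin receptor Clec4a2 (2.19, 1.61), Slamf9 (2.34, 1.57), Clec4a3 (2.64, 1.51) and the macrophage pore-forming protein Mpeg1 (1.94, 1.37). The first lower genes were SPATA45 (-2.06, -1.36), the phosphofructokinase-2 isoform Pfkfb1 (-1.87, -1.14), the lactate transporter Slc16a3 (-1.55, -1.04), the chloride transporter Clcn4 (-1.47, -1.04) and Fn3k (-1.03, -1.15). All 10 passed limma in each muscle at n = 3 arrays per group. In the AC 3 of the 10 passed without AC control 1, 3 without AC control 2, 3 without AC injury 2 and 4 without AC injury 3, and 8 to 10 without any other single array.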
